A study of Mus musculus with 8 samples.

How the data were processed

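Genomic DNA of 8 mouse livers was hybridised to 2-colour Agilent 244A oligonucleotide arrays, with the test sample in Cy3 and the reference liver in Cy5, per the labels. Per the series description, Feature Extraction software was used for data extraction and CGH analytics 3.4 for the analysis. Per the file headers of the wild-type array, the only scanner output used here, the software was Agilent Feature Extraction 9.1.3.1 with protocol CGH-v4_91, with spatial detrending and a linear dye normalisation. The deposited values of all 8 arrays are log2 ratios whose scale, centring and direction were checked on the wild-type array. There they equalled the scanner's log10 ratio, which per the file headers is red over green, with the sign turned and the base changed to log2, plus a constant of 0.0014 (r = -1 over all given values). Higher values therefore mean more test DNA. The direction of the other 7 arrays rests on the dyes in the labels, and all 28 pairs of arrays correlated above 0 (r from 0.264 to 0.760 over autosomal probes). The autosomal medians as deposited were -0.06, -0.02, -0.04, 0.00, 0.10, 0.01, -0.01 and -0.02 in tumours 1 to 6, the FEAT normal liver and the wild-type liver. The intensity values of the deposited scanner file are processed signals and mean and background signals. Its flags, which per the file headers mark dim, outlying or saturated spots, were also used. The p-value of each spot in the deposited scanner file was not used here.

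The value table holds 235406 rows, all matched to spots of the scanner file by their number. Of 2796 other spots, 2784 lie on random or mitochondrial sequence and 12 have no position. Spots of the same probe were averaged, leaving 232626 probes, of which 67.5% carry a gene name. Between 1319 and 3401 probes had no value on an array. On the wild-type array, 99.6% of spots were well above background in green and 99.9% in red. The genome build is not given in the sources used here. Gene names are those of the array, and older names were matched through a RefSeq gene table of assembly GRCm38.p6, used for names and gene neighbours only. Of 142 list genes, 132 were found.

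Each array was centred on its autosomal median, without loess or quantile normalisation. Noise was taken from differences between neighbouring probes. Values beyond 3 noise SDs of a 5-probe running median were drawn in, and each chromosome was divided by penalised least squares with a penalty of 2 times the logarithm of the probe number and at least 5 probes per segment. Segments at or beyond 0.2 in either direction were called. The threshold, the probe minimum, the tests, the gene lists and the rule for named genes were chosen before the data were examined. The penalty factor, the limit on outlying values, the averaging of spots, the GC window and the mode estimate were set once, after the files and a genome-wide plot had been seen. On simulated data with the noise of each of the 8 arrays, 0 segments were called without a planted change. The simulated noise was normal and independent between probes, so that this 0 does not give the rate of false calls on the arrays themselves. On the wild-type array, set against DNA of the same strain, 7 segments were called, all under 3 Mb. Planted shifts of 0.25 over 500 probes were recovered in 99.4% of cases and shifts of 0.5 over 10 probes in 20.5%, so that small focal changes were often below detection.

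Tumours were compared with the 2 non-tumour livers by limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjustment at 0.05, on means of 1 Mb bins with at least 20 probes and of chromosomes. In simulated data with a tumour spread of 0.05, limma recovered 100% of 100 bins shifted by 0.3 and 30% of those shifted by 0.1. With a spread of 0.12, as on the chromosomes that varied most, it recovered 28% and 3%; this second simulation was added after the results were seen. Altered shares were compared by exact permutation, with double the smaller tail as the two-sided p. Counting splits by absolute difference instead gave p = 0.357, in an exact permutation test of the same values; the first definition was kept after both had been computed. Recurrence and gene lists were tested against 10000 circular shifts along the autosomes, with list members on autosomes only. Antigen receptor loci were placed between the nearest genes named on the array.

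The named genes were Mettl13, HCC oncogenes or tumour suppressors called in at least 2 tumours and in neither non-tumour liver, the 5 highest and 5 lowest focal segments under 3 Mb, and up to 5 segments of the FEAT normal liver by size. A focal segment counted as called in a non-tumour liver at an overlap of 50% or more. Other genes in the text illustrate list counts and were chosen after their values were seen. Alternatives covered the calling threshold, penalty, probe minimum, centring, GC correction with a window of 500 kb, dim probes, bin size, control and each tumour left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0 was used. The mice are separate animals by their ages, and the labels give no batch. Each slide of this format holds 1 array, so no slide could serve as a block.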

Results

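DNA copy number was measured by array comparative genomic hybridisation in livers of male C57BL/6 mice, 6 of them hepatocellular carcinomas (HCC) of mice carrying a FEAT transgene. FEAT is another name for Mettl13, a methyltransferase gene. Of the non-tumour livers, 1 came from a FEAT mouse and 1 from a wild-type mouse, so these 2 groups have no replicates. Every sample was set against reference DNA from a healthy liver of the same strain at 6 months of age. Values are log2 ratios of test over reference, centred on the autosomal median of each array. The tumours came from mice of 16, 21, 20, 18.5, 22 and 12 months (tumours 1 to 6), the FEAT normal liver from a mouse of 13 months and the wild-type liver from a mouse of 6 months. Tumours 1 to 5 came from mice older than both non-tumour livers, so that effects of tumour and age cannot be told apart there. Per the labels, tumour 4 came with lung metastasis. After averaging of repeated spots, 232626 probes remained on 21 chromosomes, with a median spacing of 7.87 kb. The probe noise ranged from 0.22 in tumour 5 to 0.49 in tumour 4, and the small number of arrays limits the precision of all comparisons. The genome build is not given in the sources used here, and coordinates are those of the array's own annotation.

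The first comparison asked how much of the genome was gained or lost in each liver. Tumour 5 carried the most change, with 13.5% of autosomal probes in gained and 11.5% in lost segments. In tumour 1, 4.19% were gained and 10.2% lost, and in tumour 4, 4.99% were gained and 0.587% lost. Tumours 2, 3 and 6 had 0.0327%, 0.0232% and 0.0295% of autosomal probes in called segments, against 0.0323% in the FEAT normal liver and 0.0155% in the wild-type liver. The share was 7.52% ± 10.3 in tumours (SD, n = 6) and 0.0239% on average in the 2 non-tumour livers, and 4 of 6 tumours lay above both of the latter, tumour 2 by 1 probe (72 called against 71 in the FEAT normal liver). This count ranged from 3 to 5 over 8 alternatives, with 3 at either changed penalty. The difference of 7.49 percentage points had p = 0.214 in an exact two-sided permutation test over 28 splits, with the smaller tail doubled. By this definition the smallest possible p was 0.0714, so that 0.05 could not be reached. Counted by absolute difference, for which that limit does not hold, the exact permutation p was 0.357. At calling thresholds of 0.1 and 0.3, the share was 22.5% and 3.35% in tumour 1, 26.4% and 0.0336% in tumour 4, and 54.7% and 7.41% in tumour 5. At 0.1, tumour 2 had 0.823%, against 0.126% in the FEAT normal liver and 0.194% in the wild-type liver. The shares of tumours 3 and 6 did not change. The share of tumour 4 moved in both directions with other settings, to 9.25% with centring on the mode, 8.50% with a penalty factor of 1, 0.0141% with a penalty factor of 4 and 0.0336% after correction for GC content.

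**Figure D1:**
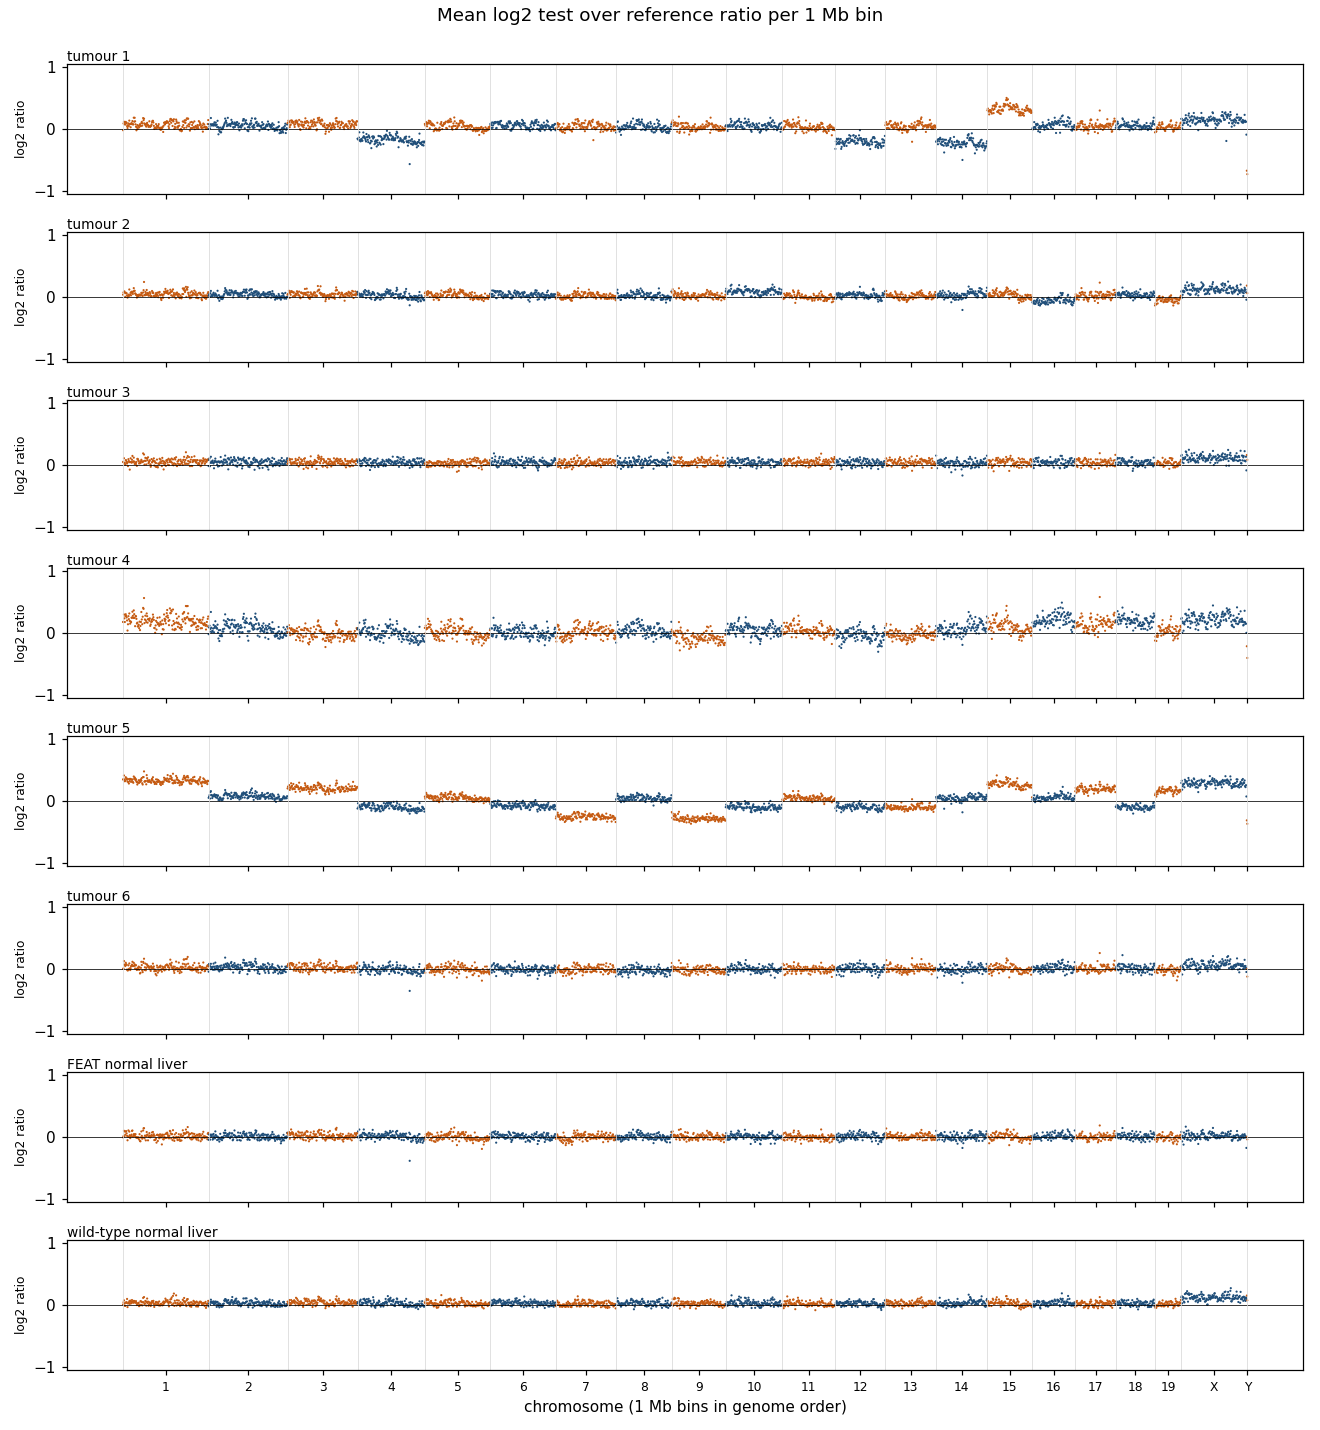
Mean log2 ratio of test over reference (vertical axis) per 1 Mb bin in genome order (horizontal axis), 1 panel per array, with colours alternating by chromosome and values limited to the range from -1 to 1. Whole-chromosome shifts are visible in tumours 1, 4 and 5, whose altered shares were 14.4%, 5.58% and 25.1%.

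Changes of whole chromosomes differed between tumours. In tumour 1, chromosome 15 stood at 0.31, while chromosomes 4, 12 and 14 stood at -0.18, -0.21 and -0.24. In tumour 5, chromosomes 1, 15, 3, 17 and 19 stood at 0.32, 0.26, 0.20, 0.19 and 0.16, and 7 autosomes lay below -0.1, with chromosomes 9 and 7 at -0.29 and -0.26 and chromosomes 4, 12, 13, 10 and 18 at -0.11, -0.11, -0.11, -0.10 and -0.10. In tumour 4, chromosomes 16, 18, 1 and 17 stood at 0.20, 0.19, 0.18 and 0.13. No autosome of tumours 2, 3 and 6 or of the non-tumour livers moved by 0.1 or more, and the largest shift in the non-tumour livers was 0.03. In tumour 2, chromosomes 10, 16 and 19 still stood at 0.08, -0.07 and -0.05. The largest autosomal shift was 0.05 in tumour 3 and 0.03 in tumour 6. The Y chromosome stood at -0.69, -0.29 and -0.33 in tumours 1, 4 and 5, against -0.02 and 0.12 in the FEAT normal and wild-type livers.

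No chromosome passed limma's test of tumours against the non-tumour livers. Chromosome 15 differed by 0.11 (SE 0.09, adjusted p = 0.843), chromosome 1 by 0.09 (SE 0.08, adjusted p = 0.843) and the Y chromosome by -0.23 (SE 0.22, adjusted p = 0.843). None of the 21 chromosomes had an unadjusted p under 0.05 in limma (0 of 21). Of 2523 bins of 1 Mb, limma called 0, and 5 had an unadjusted p under 0.05. The lone non-tumour arrays were assumed to vary like the tumours. The SD of tumours on chromosomes 1 and 15 was 0.12 and 0.13, and at a simulated spread of 0.12 limma recovered 28% of bins shifted by 0.3, so that shifts of this size could be missed.

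**Figure D2:**
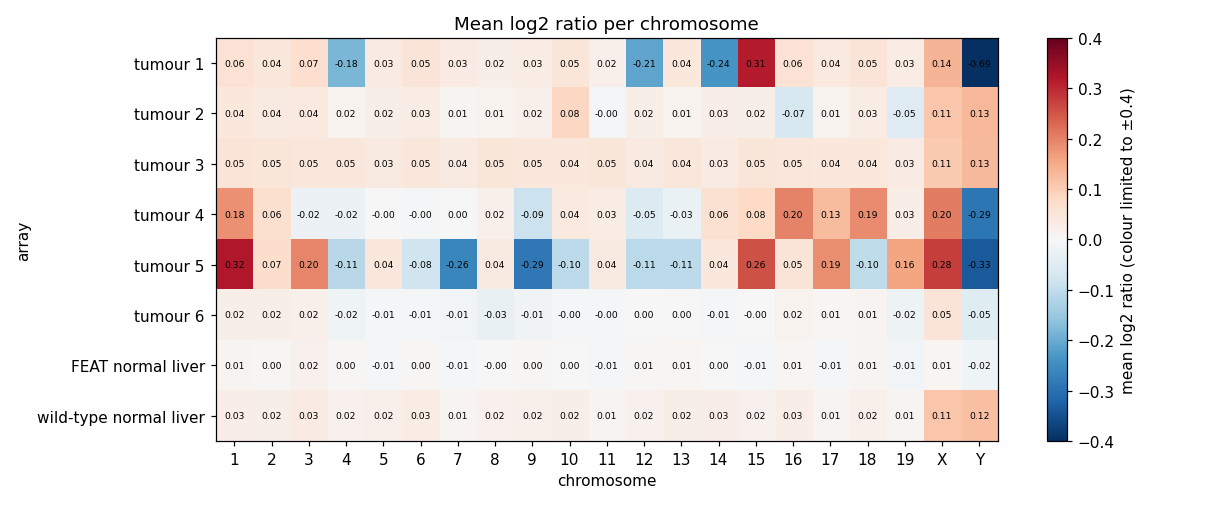
Mean log2 ratio per chromosome (columns) and array (rows), with the value printed in each cell and the colour scale limited to 0.4 in each direction. Tumours 1 and 5 both show chromosome 15 above 0, at 0.31 and 0.26, while the non-tumour livers reach at most 0.03 on any autosome.

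Recurrence was then examined over 2374 autosomal bins. Under the definition of at least 3 tumours and neither non-tumour liver, 0 bins were recurrently gained and 0 recurrently lost, at this calling threshold. With at least 2 tumours, 196 bins were gained, of which 107 lay on chromosome 1 (tumours 4 and 5) and 89 on chromosome 15 (tumours 1 and 5). Circular shifts of each tumour gave 44.3 such bins on average, with a one-sided permutation p of 0.0007 and an adjusted p of 0.0028 over the 4 recurrence tests. The 196 bins are linked bins of 2 chromosomes and not independent events. The shifts also move gains across chromosome ends, unlike gains of whole chromosomes. This p therefore cannot show how often gains of whole chromosomes would coincide. With at least 2 tumours, 7 bins were lost, all on chromosome 9 in tumours 4 and 5, against 26.6 on average in the shifts (one-sided permutation p = 0.557). Every gained bin of this count included tumour 5, and 107 were left without tumour 1, 89 without tumour 4 and 0 without tumour 5. Without tumour 4 or tumour 5, 0 lost bins were left. After the GC correction, 100 were gained and 0 lost, and the share of chromosome 1 probes called gained in tumour 4 went from 47.9% to 0%. The mean of that chromosome in tumour 4 was 0.18 before and 0.17 after, while its highest segment of at least 100 probes went from 0.30 to 0.17, under the calling threshold of 0.2.

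Genes named for HCC followed these chromosomes. Myc, which encodes a growth-promoting transcription factor, lay in gained segments of tumours 1 and 5, and the probes within 0.5 Mb of it had a mean of 0.14 ± 0.14 in tumours (SD, n = 6). Ptk2, a focal adhesion kinase gene, had 0.10 ± 0.13, and Arid2, a chromatin remodelling gene, had 0.13 ± 0.13, with the same 2 tumours gained. Keap1, which encodes a regulator of the oxidative stress response, lay in lost segments of tumours 4 and 5 and had -0.12 ± 0.15. After the GC correction its mean was -0.09 and only tumour 5 was called, 1 fewer than the 2 tumours by which the gene was named. In each of the 4 genes the SD was about as large as the mean. The only Myc probe stood at 0.00 ± 0.18, so that the call of this gene rests on its neighbours. Of 25 measured HCC oncogenes, 4 were gained and 9 lost in at least 1 tumour. The lost ones included Ccnd1, Yap1 and Ctnnb1 in tumour 5 alone. Of 22 measured HCC tumour suppressors, 2 were gained and 4 lost, the latter including Rb1 and Runx3 in tumour 1.

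Mouse orthologues of genes on human chromosome arms that are often gained or lost in HCC were tested as lists against circular shifts of their positions. All 9 orthologues of 8q genes lay in gained segments, 8 of them in 2 tumours (for Cops5, only before the GC correction), and the list stood 0.13 higher in tumours than in non-tumour livers (permutation p = 0.0097, adjusted p = 0.0792 over 12 lists). Of these, 7 were gained in tumour 1 and lie together on chromosome 15. The 13q orthologues differed by -0.10 (permutation p = 0.0132, adjusted p = 0.0792), but this rests on Ing1, measured by 1 probe on chromosome 8, which differed by -0.58 and was called in no tumour. Without it, the list differed by -0.02 (adjusted p = 0.652 with genes of at least 2 probes). Of its 7 measured members, 4 were lost in tumour 1, among them Rb1 and Lats2 (differences of -0.02 and -0.11), and Foxo1 was gained in tumour 5. Neither list passed the correction. With the probes within 0.5 Mb of each gene, the 8q list reached an adjusted p of 0.0420, and the 13q difference shrank to -0.01 (adjusted p = 0.918). The adjusted p of the 8q list ranged from 0.0420 to 0.271 over 11 alternatives.

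The other lists gave no adjusted p under 0.05 either. The 1q orthologues differed by 0.07 (adjusted p = 0.530), with 7 of 9 gained in tumour 5. The 1p orthologues differed by -0.07 (adjusted p = 0.503), with 5 of 7 lost in tumour 1. The 4q, 8p, 16q and 17p orthologues differed by 0.07, -0.01, 0.03 and 0.06 (adjusted p = 0.503, 0.739, 0.739 and 0.699). HCC oncogenes and suppressors differed by 0.01 and 0.02 (adjusted p = 0.944 and 0.739). Of 21 measured apoptosis genes, 5 were gained, among them Bcl2 and Casp8 in tumours 4 and 5, and 4 were lost (difference -0.02, adjusted p = 0.530). After the GC correction, Bcl2 and Casp8 were gained in tumour 5 only, with the segment of tumour 4 at 0.17. Of 10 hepatocyte genes, Cebpa and Apoa1 were lost (difference -0.01, adjusted p = 0.739).

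Mettl13, the transgenic gene, is named 5630401D24Rik on the array and has 2 probes on chromosome 1. The probe from 162500192 to 162500247 stood at 1.37, 1.56 and 3.73 in tumours 1 to 3 and at 2.05 in the FEAT normal liver, but at 0.26, 0.59 and 0.44 in tumours 4 to 6. It stood at -0.15 in the wild-type liver. The tumour mean was 1.32 ± 1.29 (SD, n = 6). The probe from 162506803 to 162506861 had 0.70 ± 0.30 in tumours, 0.54 in the FEAT normal liver and 0.15 in the wild-type liver. Above the median of 20 flanking probes, this second probe stood at 0.51 ± 0.20 in tumours. Whether the probes are exonic was not determined here, nor whether the transgene holds mouse sequence that they bind.

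**Figure D3:**
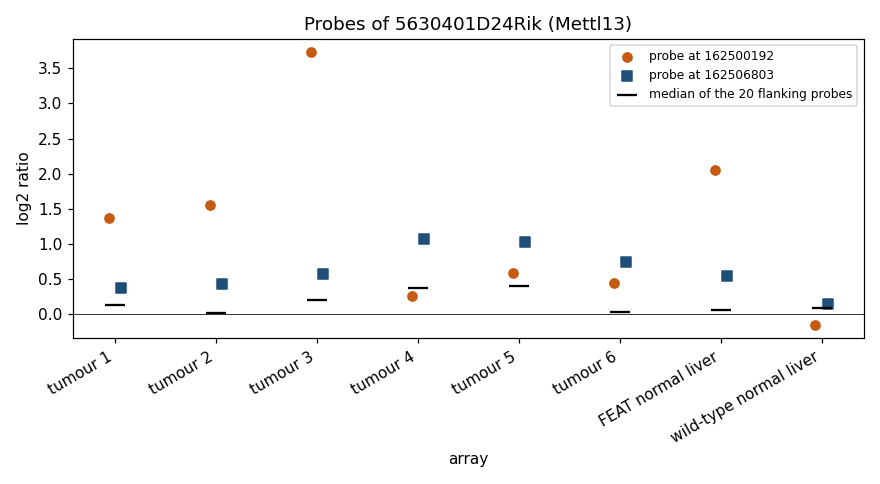
Log2 ratio (vertical axis) of the 2 probes of 5630401D24Rik in each array (horizontal axis), with dashes for the median of 20 flanking probes. The probe at 162500192 reaches 3.73 in tumour 3 and 2.05 in the FEAT normal liver and lies at -0.15 in the wild-type liver.

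The FEAT normal liver was compared with the tumours for segments that the transgenic mice share, with levels given as probe medians. It had 8 called segments, all losses. Of these, 4 were also called in at least 1 tumour and not in the wild-type liver, and 2 were called in 6 of 6 tumours. The first, from 64128347 to 64327455 on chromosome 14 with 31 probes over Loxl2, a lysyl oxidase gene, and Entpd4, stood at -1.01 ± 0.12 in tumours (SD, n = 6), -0.91 in the FEAT normal liver and -0.03 in the wild-type liver. The second, from 164750016 to 164885868 on chromosome X with 8 probes at Mid1, a ubiquitin ligase gene, stood at -1.63 ± 0.49, -1.93 and -0.02. Single probes of it reached -6.90. The 0.797 Mb loss at BC040066 on chromosome 4 was shared with 1 tumour, and for a 5-probe loss at P140 on chromosome 11 no tumour was called. Tumour 6 stood at -1.01 at P140, against -1.62 in the FEAT normal liver and -0.04 in the wild-type liver. The 5-probe loss at Abcc8 on chromosome 7 counts among the 4 only because a 43.9 Mb loss of tumour 5 covers it, so that 3 were shared by a focal call. Its probes stood at -0.55 ± 0.26 in tumours, -0.83 in the FEAT normal liver and -0.13 in the wild-type liver.

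Called segments under 3 Mb numbered 10, 9, 4, 7, 12 and 4 in tumours 1 to 6, including those shared with a non-tumour liver. Of those not called in a non-tumour liver, the highest lay at Grm4, a glutamate receptor gene, on chromosome 17. It stood at 0.86 ± 0.22 in tumours, with 5 of 6 called. Levels of segments here are medians of their probes unless called means. The FEAT normal liver stood at 0.77 there without a call, and the wild-type liver at 0.00. The next highest lay at AK006176 on chromosome X (2 tumours called), Ncoa1 on chromosome 12 (1), Usp9y on the Y chromosome (1) and Cd1d1 on chromosome 3 (2, of which 1 by an 84.1 Mb gain of tumour 5). There the FEAT normal liver stood at 0.71, 0.26, 0.40 and 0.27 and the wild-type liver at 0.11, 0.23, 0.31 and 0.36, in the same order and without calls. The tumour means were 0.48, 0.54, 0.13 and 0.38. At AK006176, tumours 2 and 5 stood at 0.94 and 1.17 with calls and tumour 6 at 0.78 without. Tumours 1, 3 and 4 stood at -0.02, -0.02 and 0.01 there. The lowest lay at C330003B14Rik on chromosome 14, at -0.62 ± 0.23 in tumours with 4 called, at -0.46 in the FEAT normal liver and at -0.04 in the wild-type liver. Smyd3 on chromosome 1 was lost in tumour 3 alone, at -0.85. A630047E20Rik on chromosome 3 (2 called), the Y chromosome (3 called) and AK019107 on chromosome 13 (1 called) followed. The Y calls of tumours 1 and 4 spanned 2.18 Mb with 527 and 561 of 606 Y probes. They cover most of the measured Y chromosome and count as focal by size alone. The counts under 3 Mb in tumours 1, 4 and 5 include such Y calls. At A630047E20Rik, tumours 1 and 5 stood at -0.72 and -0.60 with calls, and tumours 4 and 6 at -0.79 and -0.68 without. Tumours 2 and 3 stood at 0.16 and 0.23 there. The called tumour 1 stood at -0.77 at AK019107, and tumours 3 and 4 at -0.91 and -0.73 without calls. Call counts thus left out tumours at similar levels. At AK019107, tumour 2 stood at -0.32 without a call, but the mean of the same probes was -0.01. Tumours 5 and 6 stood at 0.45 and 0.58 there. They had gained calls instead, over longer segments with means of 0.58 and 0.71. Wider calls in the opposite direction also covered Ncoa1 in 1 tumour, Usp9y in 3 and Smyd3 in 1. These were a 29.0 Mb loss of tumour 1, the Y losses of tumours 1, 4 and 5 and a 192 Mb gain of tumour 5. The probes at Ncoa1 stood at 0.40 in tumour 1.

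T cell receptor and immunoglobulin loci, which lose DNA when lymphocytes rearrange them, were set against 200 probes on each side. The differences were 0.01 ± 0.06 for T cell receptor alpha and delta, 0.01 ± 0.03 for beta and 0.06 ± 0.04 for gamma (SD, n = 6). They were 0.02 ± 0.05, 0.03 ± 0.04 and -0.04 ± 0.04 for the immunoglobulin heavy, kappa and lambda loci. In the FEAT normal and wild-type livers, the alpha and delta locus stood at 0.06 and 0.05.

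The altered share was finally set against the age of the mouse. Over 6 tumours, Pearson's r was 0.331 (exact permutation p = 0.542 over 720 pairings) and Spearman's rho was 0.314 (exact permutation p = 0.564). Both adjusted p were 0.564 over the 2 measures. Without tumours 1 and 6, whose ages lay farthest from the median, Pearson's r was 0.569. Without tumour 5, r was -0.176, so that its direction rests on that tumour.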

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

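All tests of the focal regions and of the Mettl13 probe were chosen after the result was seen, as were the matches of X probes on green signal and on the mean of both signals, while the GC and red signal tests of the X chromosome were written down before their result. Of 46 groups of 6 tumours examined for a value far from the others, 6 stood out, against about 2.3 by chance. That chance level assumes independent groups that were not picked by their values. The focal segments were picked by their calls, Smyd3 through tumour 3, and some groups share a chromosome. The 6 can therefore not be set against it.

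Chromosome 7 stood at -0.26 in tumour 5 against a median of 0.01, and chromosome 14 at -0.24 in tumour 1 against 0.03. The T cell receptor beta locus stood at -0.055 (SE 0.034) relative to its flanks in tumour 3 against 0.02. That tumour also stood below the flanks at alpha and delta (-0.090, SE 0.032) and immunoglobulin heavy (-0.053, SE 0.019). It stood at -0.026 (SE 0.022) at kappa and -0.096 (SE 0.081) at lambda, but at 0.057 (SE 0.070) at gamma. The differences at kappa, lambda and gamma were thus close to their SEs in size. The focal segment at Smyd3 stood at -0.85 in tumour 3 against 0.01, and that at BC040066 at -0.70 in tumour 1 against -0.23. The segment at Loxl2 and Entpd4 stood at -1.24 in tumour 1 against -0.97. In tumour 1, the segments on either side of Loxl2 were also lost, with means of -0.23 and -0.24. The segment after BC040066 was lost at -0.22. The values of tumour 1 at these focal segments thus lie beside wider losses of the same chromosomes.

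In 4 regions, chosen from tumour calls alone, at least 4 tumours had the same focal call, as losses at Loxl2, Mid1 and C330003B14Rik and a gain at Grm4. A change arising during tumour growth should be weaker in the FEAT normal liver, whose mean was 0.925, 1.1, 0.764 and 0.602 of the tumour mean there. That liver lay 9.56, 2.26, 1.80 and 0.784 SEs beyond 50% of the tumour mean, in the same order and paired by probe. At Loxl2 and at Mid1, 5 tumours and the FEAT normal liver had calls with the same bounds. A dye or sequence bias of the probes should appear in the wild-type array. It lay nearer to 0 than 50% of the FEAT mean by 13.4, 2.60, 6.07 and 6.25 SEs, in the same order of regions. Each test rests on 1 array, with SEs over its probes, so that these explanations cannot be told apart from a difference carried by the FEAT line. Sequence variants that weaken binding were not tested, and no non-transgenic littermates were compared.

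The Mettl13 probe at 162500192 stood 4.73, 6.60 and 10.9 noise SDs above its flanks in tumours 1, 2 and 3 and 6.22 in the FEAT normal liver, but at -0.23, 0.88 and 1.14 in tumours 4, 5 and 6, so that 3 of 6 tumours did not clearly show it. The gene's other probe stood at 0.24, 0.42 and 0.36 above its flanks in tumours 1 to 3 and 0.70, 0.63 and 0.71 in tumours 4 to 6. In noise SDs, these were 0.92, 1.79 and 1.11 and then 1.43, 2.83 and 1.98, with tumour 2 above tumour 4. A reverse order of the 2 probes therefore cannot be told apart from single-probe noise. Single-probe noise is argued against for the first probe by its FEAT minus wild-type difference, at rank 21 of 229265 probes, while the other ranked 8704. A gain of the surrounding chromosome 1 is argued against by tumours 1, 2 and 3 and the FEAT normal liver, where no gain was called there. Binding of transgene sequence was not tested, and the uneven size of the first probe between FEAT arrays stays open.

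The X chromosome of the wild-type array stood at 0.07 by its median, although both DNAs came from male mice, while the median was -0.024 in the FEAT normal liver and ranged from 0.035 in tumour 6 to 0.26 in tumour 5. GC content as the whole source is argued against, since 0.829 of the offset was left after the correction. With probes matched on red signal, on the mean of both signals and on green signal, 0.169, 0.468 and 0.789 of the offset was left. A dimmer signal of single-copy X probes therefore cannot be told apart from other sources, since the outcome turns on the signal that is matched and scanner signals were at hand for the wild-type array alone. No biological explanation was tested.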

How the results depend on the processing

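The segments under 3 Mb, the array weights, gene lists without genes of 1 probe, and the GC correction and left-out tumours for the count with at least 2 tumours were alternatives chosen after seeing the data. The altered share of tumours lay above that of the non-tumour livers under all 9 alternatives, by 1.79 to 17.3 percentage points, and by 3.98 to 8.99 with each tumour left out. Its exact permutation p with the smaller tail doubled (0.143 to 0.714) could not reach 0.05 under any of them and says nothing about stability. The call of 0 bins held under 8 of 9 alternatives. Tested against 0 without the non-tumour livers, limma called 344 bins and 1 chromosome. That test takes in the offset of bin means above the median, which the wild-type liver shares. It also leaves out the error of the 2 non-tumour arrays, and these effects were not separated. With a calling threshold of 0.1, 91 bins were recurrently gained and 10 lost; with a penalty factor of 1, 5 were gained; and with at least 2 tumours, 196 were gained and 7 lost. With probes within 0.5 Mb, 1 gene list passed. With each tumour left out, the limma counts of bins and chromosomes and the count of gene lists stayed at 0. A count of 0 recurrent bins cannot change when a tumour is left out (0 in each case). The bins gained in at least 2 tumours ranged from 0 (without tumour 5) to 196, and those lost from 0 to 7. The correlation with age ranged from -0.176 to 0.529 and reversed without tumour 5. With normexp on the wild-type array, its altered share was 0.0050% in place of 0.0155%. The cause of these changes was not tested. The mean of the Mettl13 probe at 162500192 ranged from 1.32 to 1.37 over the 3 alternatives of centring, GC correction and dim probes. No tumour was left out for this mean, to which tumour 3 added a value of 3.73. Of 332 alternative values, 27 had an outcome that the design or the definition of p fixed. Of the other 305, 256 stayed on the same side or within their spread. Many of these were gene lists without a passing difference, and the tumour share had an SD of 10.3, so this tally does not measure stability. The shares of tumours 1 to 6 each held in 3, 5, 7, 2, 2 and 6 of 8 alternatives. No paired analysis was possible because the non-tumour groups hold 1 array each. A count over other splits was not made, since no comparison has 3 arrays in each group. Array noise limits short segments, most in tumour 4.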

Other observations

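The tests of the autosome levels of tumour 5 were chosen after the result was seen. These levels, as linear ratios, looked like even steps, and a share of 0.00050 (the smallest they can give) of 2000 random sets lay as close to an even ladder. That test also responds to mere grouping of chromosomes. With the 6 level groups kept and their centres redrawn, a share of 0.180 lay as close, so that even copy number steps and uneven levels cannot be told apart with so few levels.

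In bins of 1 Mb over the autosomes, tumour 6 and the FEAT normal liver correlated more closely than any other pair of arrays, at r = 0.799. Bins are not independent replicates.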
